A study of Homo sapiens with 9 samples.

How the data were processed

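The deposited tables hold estimated counts per Ensembl transcript for each library, which the authors made by aligning reads to the hg19 genome build per the labels. The aligner, the quantifier, their versions, the annotation release and whether the counting used the strand are not given in the sources used here. The tables hold 158368 transcripts with 33698 gene symbols. Counts of the transcripts of a symbol were summed per gene and rounded to whole numbers, and 15674 genes have 1 transcript. No reads were aligned or counted here. GENCODE 29, an annotation of the GRCh38 build, was used only for transcript types, lengths, GC content and gene overlaps, matched by transcript identifier for 86.9% of transcripts, and no coordinates were compared with hg19. Reads in regions where genes overlap, or of near-identical gene copies, can be assigned to either gene.

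The 4 saline and 5 TMAO libraries were compared in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 15557, and libraries were scaled by trimmed means of M values (TMM). A negative binomial model was tested with robust quasi-likelihood F tests, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change (SE) was computed as its absolute value divided by the square root of F. CPM are TMM-scaled counts per 1e+06. Log2 CPM values use a prior count of 2, and where a gene had 0 counts in a group the fold is given against a floor of 3 counts over that group. The biological coefficient of variation was 10.6%. Differences in library-level measures were tested by two-sided exact permutation over the 126 ways to split the 9 libraries.

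Lists of genes were written from general knowledge of smooth muscle, TMAO and stress biology. The 36 lists cover PERK-ATF4 targets, ATF6 and XBP1 targets, the cytosolic heat shock response, NF-kB and inflammatory cytokines, the NLRP3 inflammasome, interferon-stimulated genes, immediate early genes, apoptosis, p53 targets and senescence, FOXO1 targets, cell cycle, TGF-beta response, YAP targets and Notch targets. They also cover contractile and synthetic smooth muscle, collagens and matrix, matrix proteases and inhibitors, osteochondrogenic calcification, coagulation and fibrinolysis, cholesterol synthesis, cholesterol efflux, NRF2 and oxidative stress, hypoxia and glycolysis, oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins, autophagy and lysosome, methylamine and choline metabolism and osmolyte response. Markers of endothelial cells, leukocytes, fibroblasts and epithelium, replication-dependent histones and housekeeping reference genes completed them. Lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists. Camera was also run with a correlation estimated from the data, and fry was run as a self-contained test.

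Gene choice followed a fixed rule. The 10 largest rises and 10 largest falls past the test with a mean log2 CPM of at least 1 and groups that do not overlap are named. Up to 4 members of each list with the lowest p are named as well, with 20 genes fixed by name whatever their p, such as IL6, ACTA2 and NLRP3. The model, the filter, the lists, this rule and the alternatives below were fixed before the data were examined, except those said to be added later.

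Alternatives were scaling by relative log expression (RLE) or by library totals only, no filter, and a stricter filter of at least 10 counts in at least 4 libraries and a mean log2 CPM of at least 1. DESeq2 1.42.0, limma-voom, limma-voom with sample weights and 1 surrogate variable (sva 3.50.0) were run in place of the first model. The transcript of highest mean count stood for each gene in another run, and each transcript was tested by itself. A fold change of at least 1.5 was also required, and each library was left out in turn. Offsets for transcript length and for GC content, from splines with 6 degrees of freedom, and thinning of every library to 46709424 counts were added after the data had been seen. Genes with length and GC values were 97.2% of those tested.

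The code was tested on simulated data with 200 changed genes among 15390. It recovered 82.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 8 false calls among 195. Camera called the simulated raised list and 0 unchanged lists. A simulated length trend gave 4578 calls without offsets and 0 with them. The simulated genes varied independently, so the preset correlation of camera was not tested. Few genes were changed, as many up as down, so scaling was not tested where most genes change. The simulated trend followed the same length values that the offsets use, so its removal checks the code only.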

Results

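RNA sequencing was used to compare primary human aortic vascular smooth muscle cells exposed to trimethylamine N-oxide (TMAO) with cells given saline. TMAO is a small oxidised amine that the liver makes from trimethylamine, a product of gut bacteria. Commercially supplied cells at passage 4 were grown to 80% confluence, kept in 1% serum for 48 h and then given 100 µM TMAO or saline for 5 h, and each well of a plate was collected separately. The libraries comprised 4 saline and 5 TMAO samples. Total estimated counts per library ranged from 46.7 M to 82.2 M (M, 1e+06 counts) and averaged 57.8 ± 9.23 M for saline (SD, n = 4) and 61.5 ± 13.9 M for TMAO (SD, n = 5). This difference was smaller than the spread between libraries (two-sided exact permutation p = 0.738 over the 126 splits of the libraries, the smallest possible p being 0.00794). The labels name no donor, culture date or batch, so p-values measure only the spread between these libraries, which may be technical.

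The comparison asked which transcripts differ in smooth muscle cells after a short exposure to TMAO. After TMAO, most tested genes of the unfolded protein response, which raises the folding and degradation capacity of the endoplasmic reticulum, were higher, among them the chaperone gene HSPA5 at 9.23-fold (1417 ± 166 CPM, counts per 1e+06 scaled counts, in saline, n = 4, and 13074 ± 879 in TMAO, n = 5; mean ± SD). Of its 2 lists, 2 ATF6 and XBP1 targets and 3 PERK and ATF4 targets were lower, and camera's Benjamini-Hochberg adjusted p was 0.226 and 0.465 with an estimated correlation. Most tested genes of NF-kB signalling and immediate early genes were also higher, although camera's Benjamini-Hochberg adjusted p was 0.509 and 0.209 with an estimated correlation. Most tested genes for matrix components, matrix proteases, coagulation factors, glycolysis, mitochondrial respiration and ribosomal proteins were lower, although adjusted p was 0.513, 0.174, 0.158, 0.174, 0.174 and 0.431 with an estimated correlation (camera, Benjamini-Hochberg), and length offsets left 17 of 32 ribosomal protein genes lower. Of 15557 genes tested, 11477 (73.8%) passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5735 higher and 5742 lower with TMAO. At least a 2-fold difference was seen for 1759 of the higher and 1033 of the lower genes, and at least an 8-fold difference for 121 and 26.

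In 65.3% of all tested genes every TMAO library lay on one side of every saline library, which chance gives for 1.59% of genes. Treatment separated the libraries along the first principal component, which held 76.6% of the variance against 7.02% for the second. Spearman correlations between libraries were 0.988 to 0.998 within groups and 0.899 to 0.925 between groups. Scaling by library totals in place of trimmed means moved the median of all genes by 0.12 on the log2 scale, so fold changes smaller than this depend on which of these is used. Both scalings give relative amounts, and trimmed means take most genes as unchanged, although 73.8% passed. A larger shift shared by most genes would not be seen. Modest falls of whole lists, and the balance of higher and lower genes, are therefore relative to the other genes. The share of counts in the 100 most abundant genes was 36.5% ± 1.88 in saline (SD, n = 4) and 31.4% ± 1.30 in TMAO (SD, n = 5; exact permutation p = 0.00794).

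**Figure D1:**
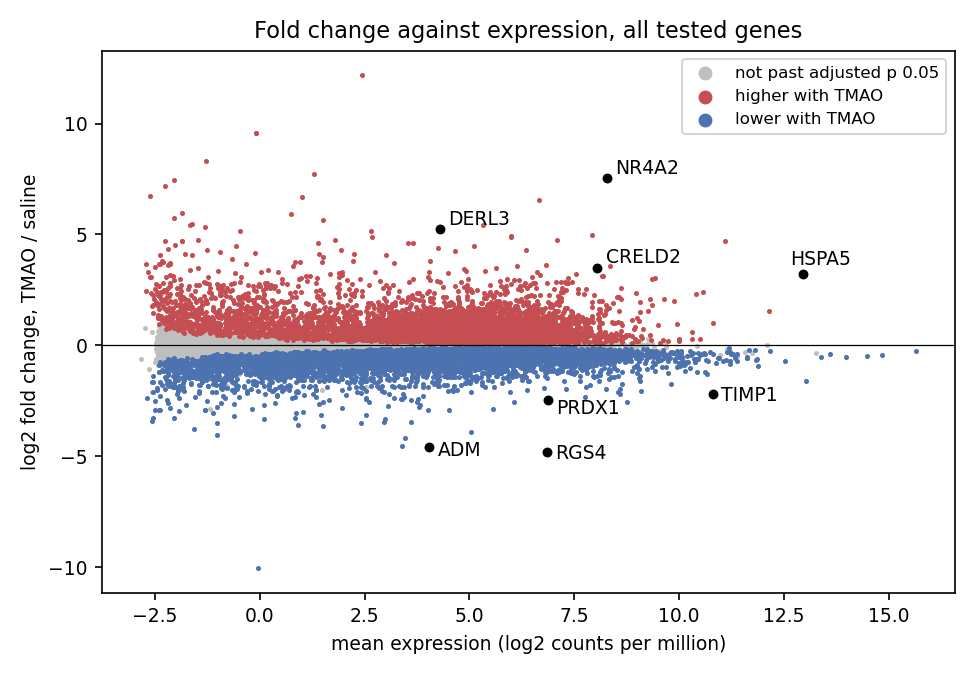
Log2 fold change of TMAO over saline (vertical axis) against mean expression in log2 CPM (horizontal axis) for each of the 15557 tested genes, with genes past an adjusted p of 0.05 in red (higher) and blue (lower) and some named genes in black. HSPA5 combines high expression with a log2 fold change of 3.21, and the points beyond 10 and below -10 belong to ZNF699 and ANKRD34A, whose counts were 0 in every library of 1 group, so that their fitted values depend on the prior count.

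The largest rises among genes at a mean log2 CPM of at least 1 included transcription factors and signalling genes with very low expression in saline. NR4A2, an orphan nuclear receptor, rose 185-fold from 3.00 ± 0.460 to 556 ± 250.0 CPM, and its relative NR4A3 rose 92.6-fold from 1.96 ± 0.350 to 180.4 ± 73.6 CPM (SD, n = 4 and n = 5). The zinc finger gene ZNF699 had 0 counts in every saline library and 410 to 1017 in the TMAO libraries, at least 706-fold higher than a floor of 3 counts over the saline group. TAC1, which encodes the precursor of substance P, rose 103-fold, from 0.0313 ± 0.0297 to 3.48 ± 2.35 CPM. Its saline libraries held 0 to 4 counts each, near the detection limit, so the size of this fold is uncertain. The hyaluronan synthase HAS1 rose 42.4-fold, the small GTPase gene RASL11B 50.5-fold, the deubiquitinase USP2 35.6-fold and the zinc finger gene ZNF331 31.7-fold. DERL3, a component of endoplasmic reticulum-associated degradation, rose 37.7-fold from 0.904 ± 0.233 to 34.5 ± 3.29 CPM. AMIGO3 rose 30.3-fold but shares exon sequence with GMPPB, which itself had a log2 fold change of 1.12, so the 2 genes cannot be fully separated by these counts. Many other named genes also overlap annotated genes or antisense transcripts, among them ZNF699, USP2, DERL3, DKK1 and GDF5 here and DDIT3, TAGLN, ACTA2 and TYMS below. The largest falls included secreted regulators of vessels and growth. RGS4, a regulator of G-protein signalling, fell 28.0-fold from 248 ± 51.6 to 8.81 ± 4.08 CPM. Transcripts for the vasodilator adrenomedullin (ADM) and the vasoconstrictor endothelin-1 (EDN1) fell 24.2-fold and 23.2-fold, from 35.4 ± 2.65 to 1.46 ± 0.226 CPM and from 22.6 ± 3.88 to 0.974 ± 0.134 CPM. SERPINB2, a plasminogen activator inhibitor, fell 18.2-fold, the WNT antagonist DKK1 15.1-fold, the bone morphogenetic protein family ligands GDF5 and BMP4 12.5-fold and 11.0-fold, the growth factor signalling antagonist SPRY1 11.0-fold and AADAC 11.1-fold. AKR1C3, a member of a family of near-identical reductases whose reads can be shared, fell 10.1-fold. Adjusted p-values of these genes lay between 8.43e-11 for ADM and 3.23e-05 for TAC1 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Single libraries set part of the size of 3 of the rises: HAS1 was 26.8-fold higher without TMAO replicate 5, TAC1 171-fold without saline replicate 3 and AMIGO3 52.9-fold without saline replicate 2. With the transcript of highest mean count in place of the sum per gene, log2 fold changes moved to 8.38 for NR4A2, 6.41 for RASL11B, 6.85 for DERL3, 5.86 for ZNF331, -5.77 for ADM and -4.70 for GDF5.

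Genes of the unfolded protein response rose together. Of 28 tested targets of the transcription factors ATF6 and XBP1, 25 were higher and 2 lower with TMAO, with a median log2 fold change of 2.08. GC offsets left 21 of these targets higher and 3 lower, and length offsets left 24 higher and 2 lower. HSPA5, the main chaperone of the endoplasmic reticulum, had a log2 fold change of 3.21 (SE 0.091, adjusted p = 3.07e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The secreted stress proteins CRELD2 and MANF rose 11.3-fold and 5.78-fold, to 446 ± 32.4 and 349 ± 12.8 CPM, and the disulphide isomerase PDIA4 rose 5.28-fold to 2374 ± 143 CPM (SD, n = 5). XBP1 itself rose 4.60-fold from 127 ± 14.9 to 584 ± 14.9 CPM, and the stress sensor kinase gene EIF2AK3 rose 4.40-fold from 50.2 ± 3.12 to 221 ± 16.5 CPM. Among 27 tested targets of the PERK and ATF4 branch, 23 were higher and 3 lower, with a median of 1.11. The transcription factors DDIT3 (CHOP) and ATF3 rose 9.33-fold and 29.9-fold, ATF4 rose 2.15-fold, and the pseudokinase gene TRIB3 rose 8.73-fold from 53.7 ± 15.7 to 468 ± 27.8 CPM. PPP1R15A, a phosphatase subunit that restores translation, rose 8.67-fold, the cystine transporter SLC7A11 5.87-fold and the folate enzyme MTHFD2 2.84-fold. Camera's Benjamini-Hochberg adjusted p was 9.31e-08 for the ATF6 and XBP1 list and 1.39e-05 for the PERK and ATF4 list, but adjusted p = 0.226 and 0.465 with an estimated correlation. The log2 fold change of CRELD2 was 2.68 when its transcript of highest mean count stood for the gene.

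Cytosolic chaperones went the other way. Of 18 tested genes of the cytosolic heat shock response, 12 were lower and 4 higher, with a median log2 fold change of -0.56 (camera, Benjamini-Hochberg adjusted p = 0.0175; adjusted p = 0.413 with an estimated correlation). The constitutive chaperone HSPA8 fell 3.34-fold from 1470 ± 45.2 to 440.3 ± 13.2 CPM (SD, n = 4 and n = 5). The mitochondrial chaperonin gene HSPE1, which overlaps HSPD1, fell 2.35-fold. The inducible chaperones HSPA1A and HSPA1B fell 3.21-fold and 2.02-fold, although reads of these near-identical copies can be assigned to either gene.

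**Figure D2:**
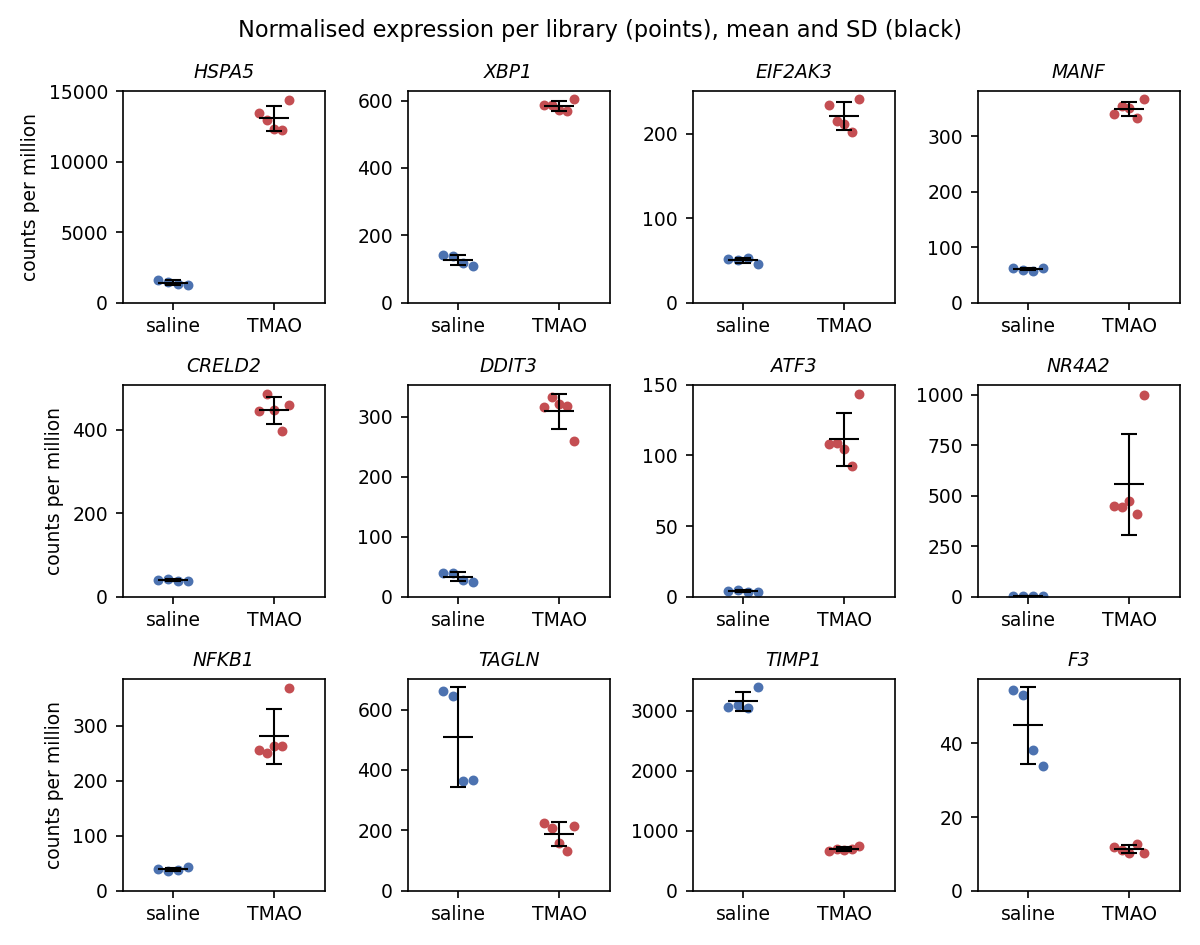
Normalised expression in CPM (vertical axis, linear and starting at 0) of 12 named genes in the 4 saline (blue) and 5 TMAO (red) libraries, with the mean and SD in black. HSPA5 lay at 1417 ± 166 in saline and 13074 ± 879 in TMAO, while TIMP1 lay at 3154 ± 164 and 694 ± 32.8.

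The enzyme IRE1 removes a short intron from XBP1 messenger RNA in stressed cells, and the annotation holds a transcript without that intron. This measurement was chosen after the gene values had been seen. The transcript without the intron held 7.51% ± 2.48 of XBP1 estimated counts in saline (SD, n = 4, range 4.18 to 9.76) and 32.3% ± 3.37 in TMAO (SD, n = 5, range 28.5 to 35.3; exact permutation p = 0.00794, the smallest possible). These shares come from estimated counts that divide reads between transcripts that are nearly alike, so their absolute level is uncertain.

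**Figure D3:**
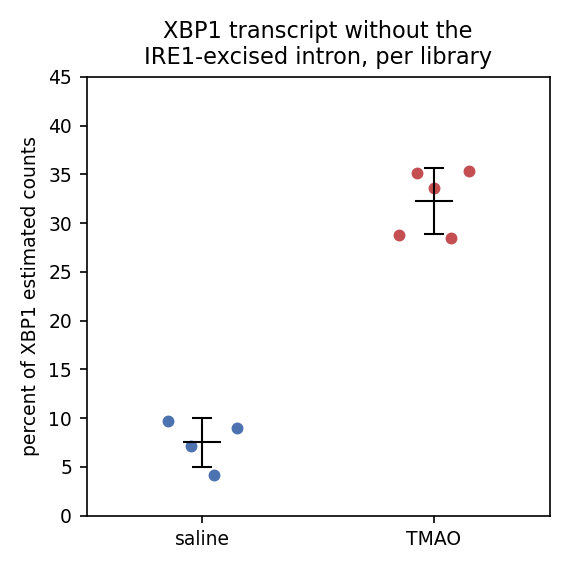
Percent of XBP1 estimated counts assigned to the transcript without the intron that IRE1 removes (vertical axis), per library, with the mean and SD in black. The 5 TMAO libraries sit between 28.5% and 35.3% and the 4 saline libraries between 4.18% and 9.76%.

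Inflammatory genes rose for the most part. Of 26 tested genes of NF-kB signalling and inflammatory cytokines, 21 were higher and 4 lower, with a median log2 fold change of 2.09 (camera, Benjamini-Hochberg adjusted p = 4.15e-04; adjusted p = 0.509 with an estimated correlation). Scaling by totals left 20 higher and 1 lower, and length offsets left 21 higher and 2 lower. The NF-kB subunit genes NFKB1, RELB and NFKB2 rose 7.25-fold, 6.31-fold and 4.90-fold, and TNFAIP2 rose 4.70-fold from 45.2 ± 1.65 to 213 ± 26.2 CPM (SD, n = 4 and n = 5). The chemokine gene CXCL8, listed under its older symbol IL8, rose 5.99-fold from 39.3 ± 38.1 to 236 ± 113 CPM (adjusted p = 0.00952, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Saline libraries differed widely for CXCL8, at 7.06, 10.3, 52.3 and 87.4 CPM in replicates 1 to 4. The size of its rise is therefore uncertain. Without saline replicate 4 the rise was 10.1-fold, and its log2 fold change was 3.52 against 2.58 when libraries were weighted by quality in limma-voom. IL6 had a log2 fold change of -0.46 (SE 0.16, adjusted p = 0.0265, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 318 ± 68.5 to 231 ± 37.9 CPM. This IL6 call was lost without saline replicate 3 (adjusted p = 0.0725), saline replicate 4 (0.0834), TMAO replicate 1 (0.0630) or TMAO replicate 2 (0.0574), by the same edgeR test, and under 4 of the other settings. CCL2, a monocyte chemoattractant, fell 1.61-fold from 154 ± 40.2 to 95.9 ± 20.5 CPM, a call lost with scaling by totals (adjusted p = 0.0656, edgeR) or length offsets (adjusted p = 0.0841, edgeR).

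Immediate early genes, which respond within minutes to hours of a stimulus, were higher in 24 of 30 cases and lower in 3, with a median log2 fold change of 0.99 (camera, Benjamini-Hochberg adjusted p = 4.15e-04; adjusted p = 0.209 with an estimated correlation). Beside NR4A2 and ATF3, the AP-1 subunit FOSB rose 24.5-fold and the zinc finger factor KLF10 7.07-fold. Inflammasome and interferon genes did not pass camera, which compares a list with other genes, but both were called lower by fry, which does not (fry with Benjamini-Hochberg adjusted p = 5.80e-04 and 0.0143). Because 73.8% of tested genes changed, fry is likely to call most lists. Of 9 tested members of the NLRP3 inflammasome list, 2 were higher and 6 lower (camera, Benjamini-Hochberg adjusted p = 0.260). The adaptor PYCARD fell 2.33-fold, CASP4 1.63-fold and GSDMD 1.39-fold, and NLRP1 rose 1.51-fold. NLRP3 itself had 3 to 18 counts per library and was too low to test. Of 22 interferon-stimulated genes, 6 were higher and 10 lower (camera, Benjamini-Hochberg adjusted p = 0.546), with IRF7 and DDX58 rising 2.61-fold and 1.61-fold and IFIT1 and IFI6 falling 2.90-fold and 1.95-fold. The median of this list was -0.075 and turned to 0.05 with scaling by totals. The log2 fold change of IRF7 was 2.57 with its transcript of highest mean count, against 1.38 for the sum.

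Markers of the synthetic smooth muscle state and of fibroblasts fell, while contractile genes did not pass camera. Of 20 tested synthetic and fibroblast-like markers, 15 were lower and 2 higher, with a median log2 fold change of -0.68. The growth factor receptor gene PDGFRA fell 4.28-fold from 649 ± 48.3 to 152 ± 17.0 CPM, the matrix proteoglycan LUM 5.92-fold, the calcium-binding protein S100A4 5.51-fold and the collagen gene COL8A1 1.99-fold (SD, n = 4 and n = 5). Of 14 tested fibroblast markers, which share PDGFRA and LUM with that list, 9 were lower and 0 higher, with a median of -0.81, and MFAP5 and FAP fell 3.03-fold and 1.67-fold. Camera's adjusted p was 0.00106 for the synthetic list and 0.00106 for the fibroblast list, and adjusted p = 0.174 and 0.226 with an estimated correlation.

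Of 22 contractile genes, 9 were lower, 2 higher and 11 did not pass, with a median of -0.39 (camera, Benjamini-Hochberg adjusted p = 0.182; fry adjusted p = 0.0153, lower). TAGLN (SM22-alpha) fell 2.72-fold from 509 ± 167 to 187 ± 39.9 CPM, the tropomyosin gene TPM2 2.02-fold, SYNPO2 2.68-fold, vinculin (VCL) 1.43-fold and the myosin kinase MYLK 1.37-fold. The myosin heavy chain gene MYH11 rose 1.35-fold at a low level, 1.20 ± 0.123 to 1.62 ± 0.107 CPM. The MYH11 call was lost with length offsets (adjusted p = 0.147, edgeR), and its log2 fold change was 2.03 with the transcript of highest mean count, against 0.43. ACTA2, the smooth muscle actin gene, measured 116 ± 66.9 CPM in saline and 66.4 ± 20.7 in TMAO and did not pass (adjusted p = 0.0931, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), but passed without saline replicate 3 (0.0464), without saline replicate 4 (0.0378), with sample weights (0.0422) and with 1 surrogate variable (0.000494), lower each time. Saline libraries differed for these genes, with ACTA2 at 191 and 153 CPM in saline replicates 1 and 2 and 63.1 and 55.8 CPM in replicates 3 and 4, against 38.3 to 85.0 CPM across the TMAO libraries.

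Matrix genes and matrix-remodelling enzymes fell. Of 26 tested collagens and matrix genes, 20 were lower and 0 higher, with a median log2 fold change of -0.43 (camera, Benjamini-Hochberg adjusted p = 2.51e-04; adjusted p = 0.513 with an estimated correlation). Thrombospondin-1 (THBS1) fell 3.02-fold from 13279.6 ± 2457 to 4404 ± 379.6 CPM, the elastin cross-linking enzyme gene LOXL1 2.42-fold, COL6A3 1.61-fold and periostin (POSTN) 1.49-fold (SD, n = 4 and n = 5). COL1A1 had a log2 fold change of -0.45 (SE 0.14, adjusted p = 0.0123, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 27 tested matrix proteases and their inhibitors, 23 were lower and 3 higher, with a median of -0.97 (camera, Benjamini-Hochberg adjusted p = 2.51e-04; adjusted p = 0.174 with an estimated correlation). The list holds enzymes and inhibitors that act against each other. The metalloprotease inhibitor TIMP1 fell 4.54-fold from 3154 ± 164 to 694 ± 32.8 CPM, the metalloproteases ADAMTS1, ADAM10 and MMP2 fell 4.99-fold, 1.96-fold and 1.30-fold, and ADAM17 rose 1.64-fold. MMP9 had 1 to 14 counts per library and was too low to test, and MMP12 was not analysed here. Of 16 osteochondrogenic genes, 11 were lower and 1 higher, with a median of -0.40 (camera, Benjamini-Hochberg adjusted p = 0.0154; adjusted p = 0.174 with an estimated correlation). This list also mixes members that act against each other, so its fall gives no direction for calcification. It was written with SPP1, MGP, TNFRSF11B and SOX9 in common with the synthetic list. Beside DKK1, the phosphate transporter SLC20A2 fell 2.15-fold, the calcification inhibitor MGP 2.47-fold and the ligand gene WNT5A 1.88-fold.

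Coagulation and fibrinolysis genes fell. Of 17 tested members, 13 were lower and 0 higher, with a median log2 fold change of -1.03 (camera, Benjamini-Hochberg adjusted p = 4.15e-04; adjusted p = 0.158 with an estimated correlation). Tissue factor (F3), which starts coagulation, fell 3.99-fold from 44.9 ± 10.5 to 11.2 ± 1.04 CPM, the thrombin receptor gene F2R 2.31-fold, the anticoagulant protein S gene PROS1 4.13-fold and annexin A2 (ANXA2), a receptor for plasminogen activation, 1.54-fold (SD, n = 4 and n = 5).

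Among signalling lists, FOXO1 targets rose, and some cell cycle genes fell. Of 15 tested FOXO1 targets, 11 were higher and 0 lower, with a median log2 fold change of 1.25 (camera, Benjamini-Hochberg adjusted p = 0.00106; adjusted p = 0.174 with an estimated correlation), including the cyclin CCNG2 at 4.04-fold, the ubiquitin ligase FBXO32 at 3.15-fold, FOXO3 at 2.10-fold and the repressor BCL6 at 1.83-fold. Of 31 tested cell cycle genes, 13 were lower, or 8 adjusted over the list alone, and 0 higher, with a median of -0.64 (camera, Benjamini-Hochberg adjusted p = 0.0175; adjusted p = 0.703 with an estimated correlation). Scaling by totals left 7 of them lower. Camera no longer called this list without saline replicate 4 (adjusted p = 0.0571), and fry did not call it (adjusted p = 0.0532). The replication clamp PCNA fell 2.57-fold, the thymidylate synthase gene TYMS 2.27-fold, MCM2 2.04-fold and cyclin D1 (CCND1) 2.38-fold. UHRF1 was not analysed here.

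Other signalling lists held members going both ways and did not pass camera, but fry called Notch, TGF-beta and apoptosis genes higher (Benjamini-Hochberg adjusted p = 3.95e-05, 0.00254 and 8.59e-04). These calls say little about these lists in particular, since fry called 32 of 36 lists. Of 13 Notch pathway genes, 9 were higher and 3 lower (camera, Benjamini-Hochberg adjusted p = 0.150), with the effector HES1 rising 29.7-fold from 0.373 ± 0.113 to 11.0 ± 1.33 CPM, MAML2 and HEY2 rising 2.10-fold and 1.64-fold, and the receptor NOTCH3 falling 3.03-fold. Length offsets gave 6 Notch pathway genes higher and 4 lower, and scaling by totals 10 higher and 1 lower. Of 24 TGF-beta response genes, 11 were higher and 8 lower (camera, Benjamini-Hochberg adjusted p = 0.546), with ID3, SMAD6 and SMAD7 rising 5.23-fold, 3.94-fold and 2.09-fold and LTBP2 falling 1.83-fold. Of 20 YAP targets, 7 were higher and 10 lower (camera, Benjamini-Hochberg adjusted p = 0.546; median -0.29, mean 0.009), with LATS2 and DLC1 rising 3.20-fold and 3.16-fold and FJX1 falling 2.51-fold. Of 20 p53 targets and senescence genes, 7 were higher and 12 lower (camera, Benjamini-Hochberg adjusted p = 0.459; median -0.31, mean 0.092). GADD45B and GADD45A had log2 fold changes of 4.32 and 1.99, CDKN2B rose 2.96-fold and TP53I3 fell 1.52-fold, a call lost with its transcript of highest mean count (adjusted p = 0.296, edgeR). CDKN1A had a log2 fold change of -0.25 (adjusted p = 0.00231, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), lost with scaling by totals (0.0731). Of 23 apoptosis genes, 11 were higher and 10 lower (camera, Benjamini-Hochberg adjusted p = 0.767), and the promoters of cell death PMAIP1 and BCL2L11 rose 3.52-fold and 3.29-fold while the inhibitors MCL1 and XIAP rose 2.19-fold and 1.94-fold. Medians of 2 of these lists changed sign with offsets, from 0.12 to -0.07 (length) and -0.03 (GC) for TGF-beta response and from 0.05 to -0.14 (length) and -0.09 (GC) for apoptosis.

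Most tested genes of energy metabolism and protein synthesis fell. Of 27 tested hypoxia and glycolysis genes, 22 were lower and 3 higher, with a median log2 fold change of -0.84 (camera, Benjamini-Hochberg adjusted p = 8.16e-06; adjusted p = 0.174 with an estimated correlation). Beside ADM, the regulator PFKFB4 fell 5.34-fold and the glycolytic enzyme genes PGAM1 and ENO1 2.24-fold and 1.84-fold. Of 26 nuclear-encoded respiratory genes, 23 were lower and 1 higher, with a median of -0.48 (camera, Benjamini-Hochberg adjusted p = 8.16e-06; adjusted p = 0.174 with an estimated correlation), among them SDHC at 2.72-fold, NDUFB3 at 2.28-fold, NDUFB8 at 1.65-fold and UQCRC2 at 1.57-fold lower. Of 12 mitochondrially encoded genes, 12 were lower and 0 higher, with a median of -0.57 (camera, Benjamini-Hochberg adjusted p = 2.59e-04; adjusted p = 0.483 with an estimated correlation), and MT-CO2, MT-ND2, MT-CO3 and MT-ND3 fell 1.63-fold, 1.60-fold, 1.51-fold and 1.48-fold. Mitochondrially encoded genes held 3.53% ± 0.0822 of counts in saline (SD, n = 4) and 2.60% ± 0.120 in TMAO (SD, n = 5; exact permutation p = 0.00794). All 32 tested cytosolic ribosomal protein genes were lower, with a median of -0.36 (camera, Benjamini-Hochberg adjusted p = 1.66e-07; adjusted p = 0.431 with an estimated correlation), such as RPL7 at 1.47-fold, RPSA at 1.43-fold and RPS3 at 1.36-fold lower. Scaling by totals left 31 of these genes lower, with a median of -0.24, and length offsets left 17 lower, with a median of -0.12. RPL27 fell 1.33-fold, a call lost with length offsets (adjusted p = 0.0551, edgeR).

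More cholesterol synthesis genes rose than fell. Of 22 tested cholesterol synthesis genes and SREBP2 targets, 13 were higher and 6 lower, with a median log2 fold change of 0.55 (camera, Benjamini-Hochberg adjusted p = 0.0428; adjusted p = 0.534 with an estimated correlation). Scaling by totals left 13 of them higher and 2 lower. HMGCS1, an early enzyme of the pathway, rose 4.95-fold, the sterol carrier STARD4 3.77-fold and NSDHL 2.79-fold, and the log2 fold change of HMGCS1 was 2.95 with its transcript of highest mean count, against 2.31. This list's call was lost with the stricter filter (camera, Benjamini-Hochberg adjusted p = 0.0564) and without saline replicate 3 (0.0667), saline replicate 4 (0.0540) or TMAO replicate 5 (0.0524). Of 16 cholesterol efflux and scavenger receptor genes, 6 were higher and 4 lower, or 3 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.754). The oxidised lipoprotein receptor OLR1 rose 24.3-fold from 0.177 ± 0.0646 to 4.43 ± 1.62 CPM, the ubiquitin ligase MYLIP 4.45-fold and the exporter ABCG1 3.32-fold, and NPC2 fell 1.65-fold. The ABCG1 call was lost with its transcript of highest mean count (adjusted p = 0.0967, edgeR).

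Of 24 tested NRF2 and oxidative stress genes, 7 were higher and 15 lower, with a median log2 fold change of -0.45 (camera, Benjamini-Hochberg adjusted p = 0.0699, or 0.0499 without TMAO replicate 5; fry adjusted p = 2.16e-08, lower). The peroxiredoxin PRDX1, which overlaps MMACHC, fell 5.54-fold and thioredoxin (TXN) 2.28-fold, while GCLC, a subunit of the glutathione-synthesising ligase, rose 3.70-fold. Of 22 autophagy and lysosome genes, 7 were higher and 9 lower (camera, Benjamini-Hochberg adjusted p = 0.517), with BNIP3, LAMP2 and LAMP1 falling 1.81-fold, 1.57-fold and 1.46-fold. The median of this list turned from -0.04 to 0.07 with scaling by totals. Lists closest to the compound itself did not pass camera. Of 21 methylamine and choline metabolism genes, 6 were higher and 11 lower (camera, Benjamini-Hochberg adjusted p = 0.25), with the choline kinase CHKA and MTRR rising 2.42-fold and 2.22-fold and ALDH7A1 and MTR falling 1.49-fold and 1.38-fold. Fry called this list lower (Benjamini-Hochberg adjusted p = 0.00278). Of 11 osmolyte and tonicity genes, 3 were higher and 3 lower (camera, Benjamini-Hochberg adjusted p = 0.782; median -0.084, mean 0.29). The tonicity factor NFAT5 rose 1.68-fold, the taurine and creatine transporters SLC6A6 and SLC6A8 fell 1.42-fold and 1.70-fold, and the betaine transporter SLC6A12 rose from 0.0127 ± 0.00855 to 0.258 ± 0.0290 CPM, near the detection limit. With scaling by totals the median of this list was 0.04, and with length or GC offsets 3 members were higher and 7 lower, with medians of -0.29 and -0.25.

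Lists of endothelial, leukocyte and epithelial markers did not pass camera. Of 13 tested endothelial markers, 8 were lower, or 6 adjusted over the list alone, and 1 higher (camera, Benjamini-Hochberg adjusted p = 0.0699, or 0.0495 without TMAO replicate 4), with PECAM1 and TEK falling 4.11-fold and 1.73-fold. ESAM rose with a log2 fold change of 2.75, or 5.06 with its transcript of highest mean count. Of 5 tested leukocyte markers, 3 were lower and 0 higher (camera, Benjamini-Hochberg adjusted p = 0.459), with CD14 falling 2.27-fold from 18.1 ± 4.00 to 7.97 ± 1.31 CPM. PTPRC measured 0.495 ± 0.123 CPM in saline and 0.631 ± 0.0813 in TMAO and passed only when saline replicate 2 was left out (adjusted p = 0.0406, edgeR) or libraries were thinned (0.0267). CD74 was lower at 0.300 ± 0.0607 against 0.172 ± 0.0564 CPM, a call lost without saline replicate 2 (adjusted p = 0.0812, edgeR), in DESeq2 (0.0732) and with length offsets (0.0587). Of 10 epithelial markers, 2 were higher and 5 lower (camera, Benjamini-Hochberg adjusted p = 0.546; median -0.15, mean 0.26), with KRT19 falling 3.28-fold and EPCAM 1.35-fold. ELF3 rose with a log2 fold change of 1.74, or 7.72 with its transcript of highest mean count. KRT17 rose 26.3-fold, from 0.0102 ± 0.0120 to 0.294 ± 0.136 CPM near the detection limit, with a log2 fold change of 4.72, or 7.13 with its transcript of highest mean count. Of 10 replication-dependent histone genes, 7 were higher and 1 lower (camera, Benjamini-Hochberg adjusted p = 0.0970, or 0.0186 with length offsets). HIST1H2AC rose 3.69-fold and HIST2H2AA3 9.18-fold, the latter a gene with a near-identical copy.

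Of 15 genes used as references for normalisation, 12 were lower and 3 higher, with a median log2 fold change of -0.31 (camera, Benjamini-Hochberg adjusted p = 0.0249, or 0.0761 with length offsets; adjusted p = 0.177 with an estimated correlation). GAPDH fell 1.79-fold from 3132 ± 114 to 1754 ± 41.4 CPM, PPIA 2.67-fold and PGK1 1.94-fold, and TBP rose 1.84-fold (SD, n = 4 and n = 5). Scaling by totals left 9 of these genes lower and 3 higher. For the 36 lists, counts adjusted over the list alone equalled those over all genes tested except where given. Camera called 19 lists with its preset correlation and 0 with an estimated correlation, and fry called 32. With 73.8% of tested genes changed, calls by fry were likely for most lists. Fry also called lower the autophagy (Benjamini-Hochberg adjusted p = 6.11e-05), endothelial (8.59e-04), leukocyte (0.00655) and epithelial (0.0149) lists, and called higher the efflux (0.00271) and histone (5.32e-05) lists. Small counts within other lists also moved: scaling by totals gave 4 contractile genes higher, 2 respiratory genes higher, 3 epithelial markers lower and 1 ATF6 and XBP1 target lower, and length offsets gave 1 hypoxia and glycolysis gene higher.

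**Figure D4:**
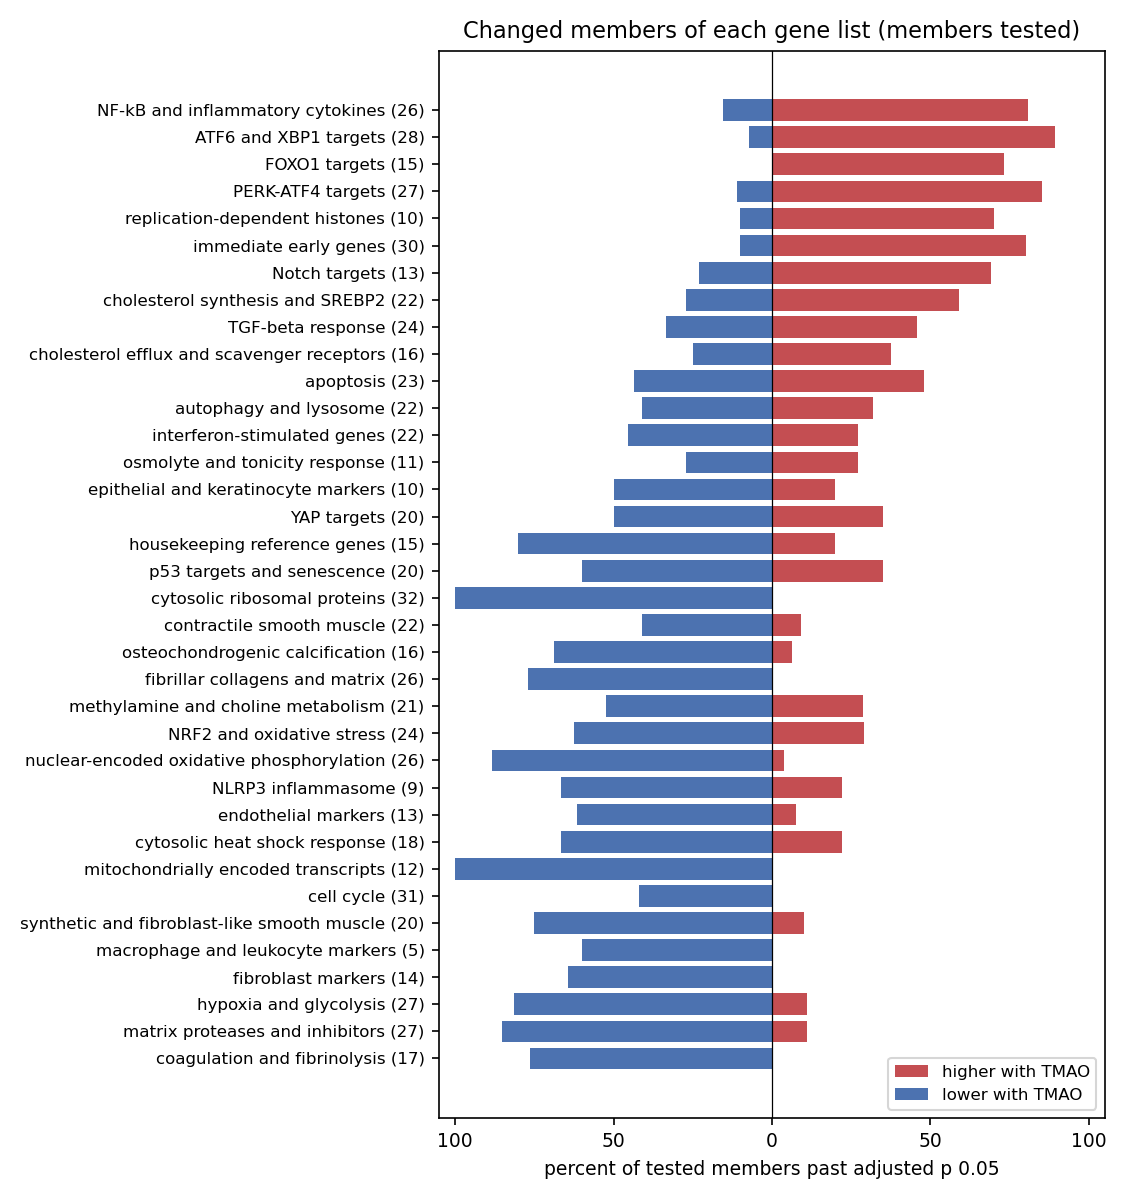
Percent of the tested members of each of 36 gene lists (number tested in brackets) that were higher (red, right) or lower (blue, left) with TMAO at an adjusted p of 0.05, sorted by the median log2 fold change of the list. The ATF6 and XBP1 list has 25 of 28 members higher, and all 32 ribosomal protein genes are lower.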

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

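Thinning, length and GC offsets and the tests of lanes, batches, scaling, other cell types and IRE1 were chosen after the result was seen. Each tested named gene was checked in both groups for 1 library standing apart from the rest, by the ratio of its gap to the range (Dixon's ratio). The same check covered total counts, the shares of the 100 most abundant and of mitochondrially encoded genes, and the XBP1 share. Of 348 groups tested, 22 stood out, and about 1 in 20 would do so by chance.

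TMAO replicate 5 stood out for 8 genes. It had the highest log2 CPM of its group for NR4A2 (9.968, the nearest other library at 8.896), NR4A3 (8.284, nearest 7.265), HAS1 (7.461, nearest 5.579), ZNF331 (9.571, nearest 8.573) and NFKB1 (8.528, nearest 8.044). It had the lowest for F2R (6.397, nearest 6.473), HIST1H2AC (3.271, nearest 3.707) and DDIT3 (8.019, nearest 8.305). TMAO replicate 4 stood out low for DERL3 (4.854, nearest 5.13), MYLK (5.98, nearest 6.056), NSDHL (5.515, nearest 5.734), PROS1 (3.27, nearest 3.366) and TRIB3 (8.71, nearest 8.902), and high for PECAM1 (0.3069, nearest -0.4451). TMAO replicate 1 was high for WNT5A (4.05, nearest 3.836) and GCLC (6.186, nearest 5.992). Saline replicate 1 was low for TNFAIP2 (5.419, nearest 5.523) and SLC6A12 (-4.907, nearest -4.359) and high for MT-ND3 (8.947, nearest 8.866). Saline replicate 3 was high for LAMP2 (7.797, nearest 7.702), and saline replicate 4 was high for TIMP1 (11.73, nearest 11.6) and LTBP2 (10.67, nearest 10.5). Apart from HAS1, leaving these libraries out did not move the fold change of these genes by more than 1.5 times.

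The broad difference between groups, 11477 genes, was weighed first. Chance is an unlikely explanation, since 1 of 100 splits drawn from the 126 possible gave as many genes, the real split itself, and the highest other split gave 7915 and grouped the 4 saline libraries with 1 TMAO library, close to the real split. Library depth, transcript length and GC content left most of the genes changed, with 11250 genes past the test after thinning, 11342 with length offsets and 11723 with GC offsets. Only 1 run and lane name was found among the libraries. An effect of TMAO may explain the difference, but so could a culture or extraction batch that follows treatment, because 0 labels name a batch, date, donor or lot.

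The rise of unfolded protein response genes was weighed next. The lowest median of the ATF6 and XBP1 list over 3 scalings was 2.075. Scaling by totals moved the median of all genes by only 0.12 on the log2 scale, so this test could hardly have come out otherwise. The list rose relative to other genes under each scaling, and a shift shared by most genes would not be seen. Length and GC trends are an unlikely cause, with a lowest median of 1.885 after offsets. For cells of another type in the TMAO wells, the highest median of the endothelial, leukocyte and epithelial lists was -0.1524. These medians could not decide, because the endothelial list had 1 member higher and 8 lower and the epithelial list 2 higher and 5 lower. The leukocyte list has 5 tested genes, and FCGR1A, a macrophage gene outside it, had 0 counts in saline and 30 to 56 with TMAO. Mean CPM fell for the named markers PECAM1, TEK, CDH5, CD14 (18.1 to 7.97), LAPTM5, CD74, KRT19 and EPCAM (14.6 to 10.8). It was higher for ESAM, PTPRC, ELF3 and KRT17, but reached only 0.7098, 0.631, 0.986 and 0.294 with TMAO. Some falling markers were well expressed in saline, TEK at 41.4 and KRT19 at 48.4 CPM, so their falls alone do not measure added cells. Meanwhile 25 of 28 ATF6 and XBP1 targets rose, with PDIA4 going from 449 to 2374 CPM. These levels argue against endothelial, leukocyte or epithelial cells as the source of the rise. Cell types without markers here stay open. Activation of IRE1 is a candidate explanation, since the share of XBP1 counts on the transcript without the intron was 24.75 points higher with TMAO. Whether TMAO itself or another difference between the wells set off this stress cannot be told from 0 labels that name a batch.

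Transcripts annotated as targets of nonsense-mediated decay (NMD), which removes messages with early stop codons, held 1.77% ± 0.0495 of counts in saline (SD, n = 4) and 2.28% ± 0.0842 in TMAO (SD, n = 5; two-sided exact permutation p = 0.00794). The rise was not particular to them. Transcripts not matched to the annotation went from 5.43% to 5.99% and processed transcripts from 1.41% to 1.60%, while coding transcripts went from 88.2% to 87.0% (exact permutation p = 0.00794 for each). Retained-intron transcripts went from 2.87% to 2.76% (exact permutation p = 0.0714). A few abundant genes are an unlikely cause, as the share within the gene rose in 0.6603 of 2611 genes. More unspliced RNA was not seen on annotated retained-intron transcripts, whose share within the gene rose in 0.3734 of 3490 genes. Unspliced RNA outside annotated transcripts was not counted, so it stays open. Reduced NMD could explain the rise, since genes held down by NMD, among them UPF1, SMG1, SRSF3 and TRA2A, had a median log2 fold change of 0.6356, but 0 of the snoRNA host genes that made up 1 of the 3 sets of this test could be tested. Values of the tested genes are sums over all transcripts of a gene, so the forms that NMD removes were not measured apart. These genes could also have risen for other reasons, because HNRNPA2B1 and SRSF2, in the same sets, had log2 fold changes of -0.60 and -0.17. SMG6, also in these sets, did not pass (log2 fold change 0.099, adjusted p = 0.0541, edgeR).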

How the results depend on the processing

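Offsets for length and GC content and thinning were chosen after the result was seen, and the other settings before. The number of genes changed by TMAO stayed between 9725 (stricter filter) and 11961 (1 surrogate variable) with gene-level settings, and between 11039 and 11361 when 1 library was left out. Tested by itself, each transcript gave 21967 in place of 11477 genes changed by TMAO, 11456 in place of 5735 genes higher with TMAO and 10511 in place of 5742 genes lower with TMAO, because more units are counted. A change of at least 1.5-fold left 6244, 3422 and 2822. Scaling by totals made 58.5% of changed genes higher, against 50.0%. Length and GC offsets made 45.6% and 44.9% higher. The lists called went from 19 to 0 with an estimated correlation, which takes into account that genes of a list vary together, to 32 with fry, which does not compare a list with other genes, and to between 17 and 20 when 1 library was left out. Fry gave the opposite direction for p53 targets (adjusted p = 0.1918, fry with Benjamini-Hochberg adjustment), YAP targets (0.5607) and osmolyte response (0.1389), whose means and medians differ in sign. Across named genes 3532 values kept their direction and their side of the adjusted p threshold, 6 gained a call, 18 lost a call and 0 reversed direction. Across lists these counts were 526, 17, 26 and 3. A kept call does not mean a kept size, which moved for genes such as ELF3 and ESAM above. Most named genes were chosen for a low p or a large change in these data, so their calls were likely to be kept. The difference in library totals, 3.675 M, lay between -1.503 M without TMAO replicate 1 and 7.552 M without saline replicate 2, because the former is the deepest library and the latter the deepest of its group. For changes of single genes the cause was not tested. No paired analysis was possible because the labels give no replicate numbers that groups share. Depth limits genes such as NLRP3 and MMP9, which had at most 18 counts in a library.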

Other observations

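The items below were chosen after their values were seen. Of 487 tested zinc finger genes with ZNF symbols, 320 were higher and 64 lower, with a median log2 fold change of 0.55. The median was 0.45 with length offsets, 0.47 with GC offsets and 0.67 with scaling by totals. Of the 7 tested NMD factors that NMD itself holds down, 6 were higher, with UPF2 at a log2 fold change of 0.73 and UPF3B at 0.84. Of 7 RNA-binding protein genes with poison exons 5 were higher and 2 lower, and of the snoRNA host genes looked for 0 were tested.

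Some genes had estimated counts of 0 in 1 group, and whether this depends on how reads were divided between similar or overlapping transcripts was not tested. With a mean count above 20 in the other group, 5 genes had 0 counts in every saline library and 1 in every TMAO library. Beside ZNF699, the histone genes HIST2H3A and HIST2H3C, which hold identical values, measured 1.58 ± 0.133 CPM with TMAO (SD, n = 5), at least 116-fold above the floor. FCGR1A, a macrophage receptor gene, had 30 to 56 counts and HMX3 14 to 33 counts in the TMAO libraries, at least 49.0-fold and 26.7-fold above it. ANKRD34A measured 2.19 ± 0.446 CPM in saline (SD, n = 4) and 0 with TMAO, at least 233-fold lower.

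Longer transcripts rose slightly more than shorter ones, with a Spearman correlation of 0.188 between log2 fold change and transcript length across genes, and -0.183 for GC content. Libraries of both groups spread along the second principal component. It placed saline 1 to 4 at 24.1, 14.8, -13.0 and -22.4 and TMAO 1 to 5 at 7.27, 2.20, -7.32, -21.7 and 16.2. ACTA2 measured 85.0, 74.1, 51.3, 38.3 and 83.3 CPM and TAGLN 225, 208, 157, 133 and 213 CPM in TMAO 1 to 5, and in saline 1 to 4 they were highest in 1 and 2. The mean chi-square per gene between replicates was 6.05 for saline 1 and 2 and 13.1 for saline 3 and 4, against 43.3 to 72.5 across the pairs.

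The transcript changes resemble an endoplasmic reticulum stress response, with the median of the ATF6 and XBP1 list at 1.885 or more under every offset. Whether this goes along with the fall of secreted matrix genes such as TIMP1 and THBS1 was not tested. At a single dose and time, and with RNA only, the order of events cannot be told. A second, labelled batch with libraries of both groups, and measurements at earlier times, would separate treatment from batch. Measuring phosphorylated EIF2AK3 and spliced XBP1 directly would test the stress response.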
